A study of Mus musculus with 6 samples.

How the data were processed

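RNA from cultured aortic smooth muscle cells of wild-type and FHL2-knockout C57Bl/6 mice was measured on 1-colour Illumina expression beadchips, with biotin-labelled cRNA. Per the labels, each culture batch held cells pooled from 3 aortas, so that the 3 batches of a genotype came from 9 mice, and RNA was taken after 48 h without serum. Each of the 6 samples was 1 array. Samples were grouped by the genotype and numbered by the replicate number in their labels.

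The deposited intensity table holds 1 summarized bead intensity per probe and array, with no background subtracted and no scaling between arrays, as its values show. Beside each intensity the authors deposited a detection p-value, which per the file headers is given per probe and array. It takes values in 936 equal steps, as a rank against negative control beads would give. A matrix of values on the log2 scale was also deposited, and its columns share nearly the same quantiles, so that it had been normalized between arrays. The submitters' processing notes name GenomeStudio 2011.1, R 2.14.0 and limma 3.10.2 without their roles. How the matrix was background-corrected is not given in the sources used here. After the normalization used here its columns correlated at 0.999 with the array they name, and their medians lay between 4.94 and 4.95, which leaves the offset behind its scale unknown. It served as an alternative source of values.

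Raw intensities were normalized in R 4.3.3 with limma 3.58.1. The neqc procedure estimated the background from the detection p-values, corrected it by normexp, added an offset of 16, made the intensity distributions of the 6 arrays equal by quantile normalization and took log2. This step assumes that the distribution of intensities was alike in both genotypes, and the offset shrinks fold changes of dim probes. A probe was kept when its detection p was under 0.05 on at least 3 of the 6 arrays. Of the 45281 probes, 15527 passed. Gene symbols came from the platform annotation supplied with the values, updated by gene identifier through a RefSeq table of the mouse assembly GRCm38.p6. This gave 1 symbol for 34885 probes, several for 18 and none for 10378, and 34807 probes were matched by identifier. Of the kept probes, 2150 had no single symbol and are counted but not named. The RefSeq table also gave chromosomes and neighbouring genes, but the build behind the probe design was not given in the sources used here, and positions are not printed.

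Differences were tested per probe with limma's lmFit and eBayes, knockout minus wild-type, with equal weights, and adjusted by the Benjamini-Hochberg method over the 15527 probes. An adjusted p under 0.05 is called higher or lower. All adjusted p-values given for genes are from this limma fit. The errors of log2 fold changes are moderated standard errors, those of group means are standard deviations, and n = 3 arrays per genotype. The 9051 genes with a kept probe are represented by their brightest kept probe over all 6 arrays, and other kept probes that differed in their call are named. Where a probe was not detected on any of the 3 arrays of a genotype, the fold is a bound, written "at least". It sets the mean of the detected group against the mean over the other group's arrays of the higher of the probe's own value and the lowest value among detected probes.

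A total of 42 gene lists (pathways, complexes and cell type markers) were written before the data were examined. The 34 lists with at least 5 measured genes were tested with camera at its preset inter-gene correlation of 0.01, which compares a list with all other genes, and adjusted over those 34 lists. Counts of members are over all probes tested, and counts adjusted over the list alone stand beside them. Alternatives were camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. A further 4 lists were drawn up after the data were seen and are used only in the closing section.

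Named genes followed a rule fixed before the data were examined. It took Fhl2 with all its probes, the 15 largest rises and 15 largest falls among called genes whose groups did not overlap, up to 4 members of each list with the smallest p, up to 10 called genes within 20 Mb of Fhl2, and Actb, Gapdh and Rplp0. Alternatives covered the background correction, the normalization, the authors' matrix, the filter on dim probes, the variance model, array weights, the replicate number as a block, leaving out each array, a fold threshold of 1.5 and the averaging of probes. Slides and scan dates were not given in the sources used here, so no batch could be tested.

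The fit was tested on simulated data with the means and spreads of the 15527 real probes and 3 arrays per group. It recovered 12% of the probes changed by 0.5 on the log2 scale, 94% of those changed by 1, and 100% of those changed by 2 or by 4, with 50 probes per size. Of its 162 calls, 9 were false. The number of arrays limits the precision, and in the simulation changes well under 1 on the log2 scale were often missed. The simulation changed 50 probes per size, a far smaller share than the 29.6% called in the real data. Its threshold was therefore stricter, and its recovery of small changes does not carry over to the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.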

Results

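Gene expression was profiled in smooth muscle cells cultured from mouse aorta, to learn what the LIM-only protein FHL2 does in these cells. LIM-only proteins consist of zinc-binding LIM domains and act as adaptors for other proteins. Cells of 3 wild-type and 3 FHL2-knockout batches were compared, each on 1 array, after 48 h without serum. Median raw intensity ranged from 116 in wild-type replicate 2 to 172 in wild-type replicate 1, and 14844 to 16115 of 45281 probes were detected per array. After normalization, arrays of the same genotype correlated at 0.985 to 0.988 across probes, and arrays of different genotype at 0.934 to 0.939. The first principal component held 74.7% of the variance.

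Fhl2, on chromosome 1, was strongly reduced in all 3 knockout arrays. Its brighter probe, ILMN_2770386, averaged 11.37 ± 0.14 (SD, n = 3) on the log2 scale in wild-type and 6.80 ± 0.21 (SD, n = 3) in knockout cells, a change of -4.57 ± 0.15 (SE) or 23.8-fold lower, with a limma adjusted p of 9.66e-07. This probe was still detected on all 3 knockout arrays. The dimmer probe, ILMN_1213912, was detected on all 3 wild-type arrays and on 0 of the 3 knockout arrays, at least 8.12-fold lower. Which part of the gene was deleted and where the probes lie in it is not given in the sources used here, so the remaining signal of the brighter probe cannot be assigned to a transcript.

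The genotypes differed widely. Of 15527 probes, 2235 were higher and 2361 lower in knockout cells, 29.6% of the probes tested, and 685 rose and 813 fell by at least a factor of 2. These probes stood for 1505 genes that were only higher and 1627 that were only lower, and a further 17 genes had probes in both directions. The groups did not overlap for 44.4% of probes, against 10% by chance. Without knockout replicate 2 the number of higher probes was 1468, and without wild-type replicate 2, the dimmest array, the number of lower probes was 1505.

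**Figure D1:**
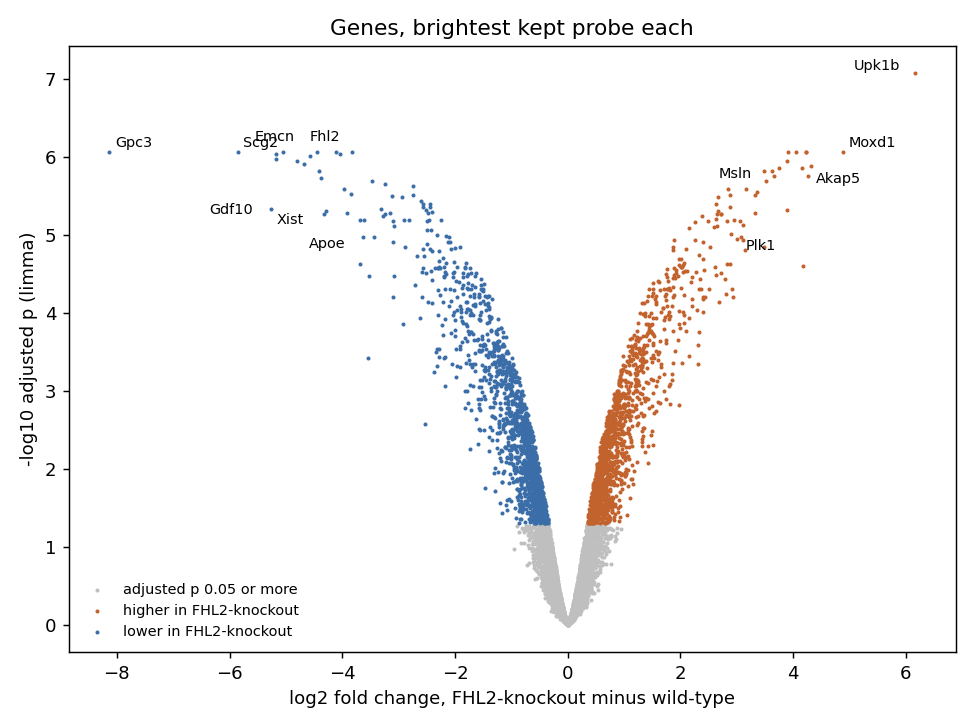
Log2 fold change of each gene's brightest kept probe (x axis, knockout minus wild-type) against -log10 of its limma adjusted p (y axis). Orange points were higher and blue points lower in knockout cells at an adjusted p under 0.05. Upk1b lies farthest right at 6.17 and Gpc3 farthest left at -8.13, both fitted changes that depend on the offset because Upk1b in wild-type and Gpc3 in knockout cells was at background.

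The largest rise in knockout cells was that of Upk1b, a uroplakin of urothelium. It was not detected on any wild-type array and was at least 45.6-fold higher in knockout cells. Moxd1, a monooxygenase related to dopamine beta-hydroxylase, and Cib3, a calcium-binding protein, were likewise not detected in wild-type and at least 19.4-fold and 13.9-fold higher. Bounds for Ppl (periplakin, a desmosome-associated protein), Ffar4 (a receptor for long-chain fatty acids), the cytokine gene Il33 and the hydroxysteroid dehydrogenase Akr1c18 were 14.01-fold, 11.0-fold, 9.65-fold and 7.41-fold. Akap5, which anchors protein kinase A, rose 19.3-fold, the aldehyde dehydrogenase Aldh3a1 18.7-fold, the sodium pump subunit Atp1b1 17.9-fold, the smooth muscle gamma-actin Actg2 14.8-fold and the microtubule-associated protein Map2 13.5-fold. The filamin-binding Rflna, detected on 1 of 3 wild-type arrays with a wild-type mean at background, rose by 3.66 on the log2 scale. Pbp2, detected on 2 of 3 wild-type arrays, rose 18.0-fold, but its probe may not be told from close relatives of the gene. Nme7 rose 14.8-fold by its brightest probe and by 4.14 and 4.64 on the log2 scale by 2 others, the latter detected on 1 of 3 wild-type arrays, whereas 3 probes gave -0.06, -0.12 and -0.09 without passing and 1 fell by 1.22. A further Ppl probe, with a wild-type mean at background, gave 0.63 (adjusted p = 0.0587). The adjusted p of these 15 genes was 2.49e-05 or less.

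The largest fall was that of Gpc3, a cell-surface heparan sulfate proteoglycan. It fell by 8.13 ± 0.25 (SE) on the log2 scale, from 13.23 ± 0.14 (SD) in wild-type cells, and was detected on 1 of 3 knockout arrays, with a knockout mean at background, so that the size of this fitted change depends on the offset. Its other kept probe was not detected in knockout cells and was at least 181-fold lower. Scg2, a secretogranin, was 57.8-fold lower, the TGF-beta family member Gdf10 38.4-fold, the secreted protein Mia 33.1-fold, the cartilage matrix protein Comp 28.0-fold, lipoprotein lipase (Lpl) 25.6-fold, the receptor activity modifier Ramp2 20.8-fold and the soluble epoxide hydrolase Ephx2 17.3-fold. Not detected in knockout cells were Dlk1, a Notch-like ligand (at least 30.5-fold lower), the endothelial sialomucin Emcn (at least 27.9-fold), Esm1, a proteoglycan secreted by endothelium (at least 15.4-fold), Xlr4a (at least 15.03-fold, with near-identical gene copies that the probe may also bind) and Xist (at least 14.1-fold). Dpysl4, detected on 2 of 3 knockout arrays, was 19.6-fold lower by its brightest probe, while another kept probe gave 0.42 (adjusted p = 0.101). With Fhl2 these made up the 15 largest falls, all with an adjusted p of 5.36e-06 or less.

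**Figure D2:**
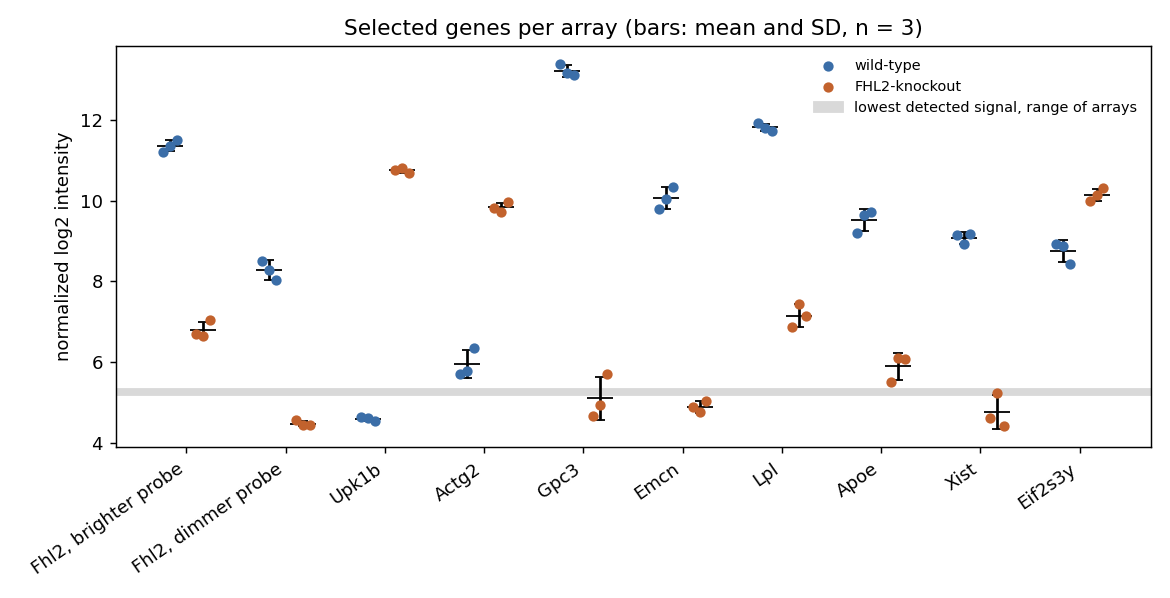
Normalized log2 intensity of 10 probes on each array (points), with mean and SD of the 3 wild-type (blue) and 3 knockout (orange) arrays, and the range over arrays of the lowest detected signal as a grey band. Both Fhl2 probes, Gpc3, Emcn, Lpl, Apoe and Xist lie lower and Upk1b, Actg2 and Eif2s3y higher on all 3 knockout arrays.

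Of the 34 tested gene lists, 5 were higher and 3 lower in knockout cells by camera at its preset correlation. With an estimated correlation, 0 were higher and 0 lower. Cell cycle genes were higher as a group in these cells kept without serum. Of 17 measured, 14 were higher and 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 8.78e-09; adjusted p = 0.0947 with an estimated correlation). The mitotic kinase Plk1 rose 8.03-fold, the anaphase activator Cdc20 6.63-fold and the centromeric histone Cenpa 4.47-fold, and thymidine kinase Tk1 was at least 2.98-fold higher. The list's median change was 1.48, or 1.15 with the 4 members not detected in wild-type set to their bound. Cholesterol biosynthesis genes also rose, 13 of 17 with 0 lower (14 and 0 adjusted over the list alone; camera adjusted p = 1.12e-07; adjusted p = 0.0947 with an estimated correlation). Msmo1 rose 6.04-fold, Fdps 5.04-fold, Hsd17b7 3.81-fold and Cyp51 3.50-fold.

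Hypoxia and glycolysis genes were higher in 15 of 19 cases and lower in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 2.46e-06; adjusted p = 0.0947 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase detected on 2 of 3 wild-type arrays, rose 5.09-fold and the angiogenic factor Vegfa 3.71-fold. Carbonic anhydrase Car9, detected on 1 of 3 wild-type arrays with a wild-type mean at background, rose by 2.21 on the log2 scale, whereas Adm, which codes for adrenomedullin, was 4.44-fold lower. Of 20 genes of the ER stress and amino acid response, 11 were higher and 1 lower (12 and 2 adjusted over the list alone; camera adjusted p = 4.93e-04; adjusted p = 0.0947 with an estimated correlation). The serine synthesis enzyme Psat1 rose 4.06-fold and Ddit4, an inhibitor of mTORC1, 3.95-fold. Pdia6 and Trib3 rose 2.16-fold and 3.36-fold by their brightest probes, while another probe of each gave -0.07 and 0.47 without passing. That of Trib3 had a wild-type mean at background.

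The lists that were lower held bone and cartilage genes, antigen presentation genes and endothelial markers. Of 13 osteogenic and chondrogenic genes, 9 were lower and 0 higher (10 and 0 adjusted over the list alone; camera adjusted p = 4.12e-05; adjusted p = 0.107 with an estimated correlation). Comp was 28.0-fold lower, the type II collagen gene Col2a1 3.33-fold, and Cytl1 was at least 4.71-fold lower. Mgp, an inhibitor of calcification, fell by 1.63 on the log2 scale. Of 12 genes of MHC class I and antigen presentation, 7 were lower and 0 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0183; adjusted p = 0.182 with an estimated correlation). The immunoproteasome subunit Psmb9 was 2.44-fold and the peptide transporter Tap2 2.02-fold lower, and Psmb8, detected on 1 of 3 knockout arrays with a knockout mean at background, fell by 2.27 on the log2 scale. H2-M3 was 2.26-fold lower, and its probe may also bind related MHC genes.

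**Figure D3:**
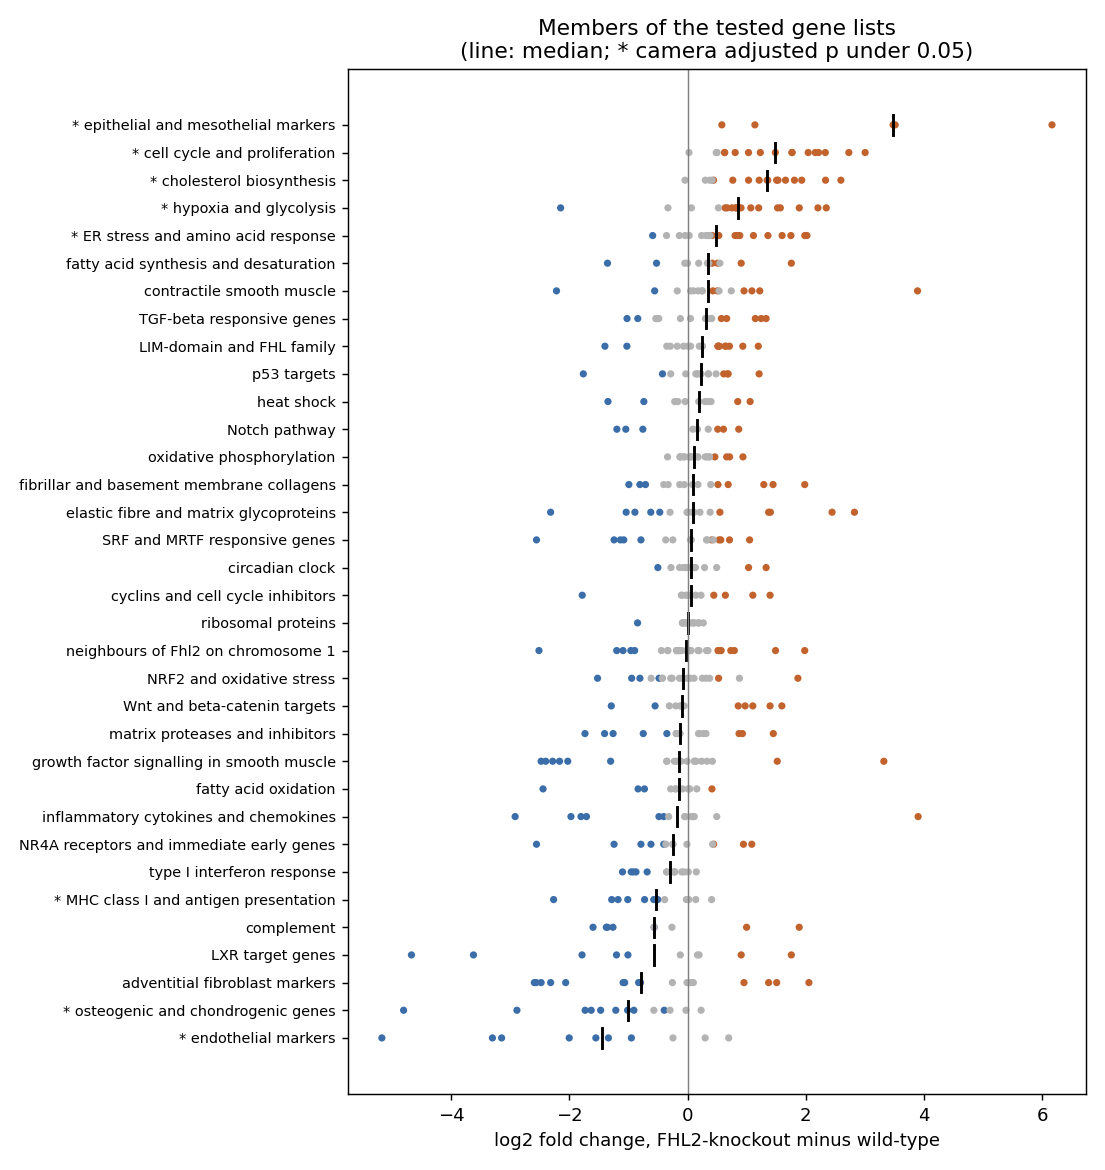
Log2 fold changes (x axis, knockout minus wild-type) of the measured members of the 34 tested gene lists (rows), with orange points higher, blue points lower and grey points not passing, the list median as a black line and an asterisk at lists with a camera adjusted p under 0.05. The medians of these fitted values run from -1.45 for endothelial markers to 3.48 for epithelial and mesothelial markers, and with members undetected in 1 genotype at their bound these were -0.99 and 2.84, and the osteogenic list was lowest at -1.02.

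Markers of other cell types moved with the genotype in both directions. All 5 measured epithelial and mesothelial markers were higher (5 and 0 adjusted over the list alone; camera adjusted p = 4.12e-05; adjusted p = 0.0947 with an estimated correlation). Besides Upk1b, mesothelin (Msln) was at least 7.15-fold higher, Upk3b rose 11.1-fold and E-cadherin (Cdh1), detected on 2 of 3 wild-type arrays, 2.20-fold. Of 10 measured endothelial markers, 7 were lower and 0 higher (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 7.32e-04; adjusted p = 0.0947 with an estimated correlation). Emcn, Egfl7, Esam and Icam2 were detected on all 3 wild-type arrays and on 0 knockout arrays, at least 27.9-fold, 7.71-fold, 6.08-fold and 2.73-fold lower. With undetected members at their bound, the medians were 2.84 and -0.99. Of 13 epithelial and mesothelial genes with a probe, the filter kept only these 5. Of them, 3 were kept through detection on the knockout arrays alone, and 7 of the 10 endothelial markers through the wild-type arrays alone. The counts and camera p-values of both lists therefore rest in part on members chosen by the genotype in which they were high.

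Of 17 adventitial fibroblast markers, 4 were higher and 9 lower (4 and 9 adjusted over the list alone; camera adjusted p = 0.0908). Scara5 and the growth factor receptor Pdgfra were 6.04-fold and 5.58-fold lower and Clec3b at least 4.62-fold lower, while Pi16 rose 4.15-fold. Lists with fewer than 5 measured genes were not tested. Among 4 macrophage and leukocyte markers, 1 was higher and 2 lower (1 and 2 adjusted over the list alone): the lysozyme genes Lyz1 and Lyz2, near-identical copies, were 4.99-fold and 5.33-fold lower and the endotoxin co-receptor Cd14 1.91-fold higher, and Csf1r gave 0.00 ± 0.14 (SE). Among 3 adipocyte markers, 0 were higher and 2 lower (1 and 2 adjusted over the list alone): Pparg was 4.24-fold and Plin4 2.61-fold lower. Among 4 striated muscle markers 1 was lower (0 and 1 adjusted over the list alone), Acta1, which fell by 1.78 on the log2 scale and was detected on 1 of 3 knockout arrays with a knockout mean at background, and Mb, detected on 2 arrays of each genotype, gave 0.06 ± 0.22 (SE). Among 4 neural and Schwann cell markers, Mbp was at least 2.30-fold higher and Egr2 at least 2.07-fold lower (1 and 1 adjusted over the list alone). Ncam1 gave -0.06 ± 0.25 (SE) by its brightest probe, while another of its probes was lower, by -1.31. The only measured lymphocyte marker, Cd2, was not detected in knockout cells. It was at least 1.10-fold lower and did not pass (adjusted p = 0.0511, 0 and 1 adjusted over the list alone). Of the 10 erythroid markers, 0 were measured.

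Sex-linked marker genes also differed. Xist, which is transcribed from the inactive X chromosome of female cells, was detected by 4 of 4 kept probes on all wild-type arrays and by 0 on the knockout arrays. The Y-linked genes Eif2s3y and Kdm5d were detected in both genotypes and rose in knockout cells by 1.40 ± 0.17 (SE) and 0.79 ± 0.14 (SE) on the log2 scale, and Uty, detected on 2 wild-type arrays and 1 knockout array, gave 0.28 ± 0.24 (SE). Over the list of 4 measured genes, 2 were higher and 1 lower (2 and 1 adjusted over the list alone). The sex of the mice is not given in the labels. This difference and those in markers of other cell types ran with the genotype and stand beside every gene group described.

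Genes of smooth muscle contraction did not pass as a list (camera adjusted p = 0.0728), with 6 of 16 higher and 2 lower (7 and 2 adjusted over the list alone). Besides Actg2, tropomyosin Tpm2 rose 2.33-fold and leiomodin Lmod1 2.13-fold, whereas Mustn1 was 4.66-fold lower. Of 20 genes of the LIM-domain and FHL family, Fhl2 itself not counted, 9 were higher and 2 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.161). Csrp1 rose 2.29-fold and zyxin (Zyx) 1.63-fold, and Lmo2 and Lmo7 were at least 1.61-fold and 1.26-fold lower. Targets of SRF and MRTF went both ways, 5 of 17 higher and 5 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.978; median 0.06, mean -0.18). Filamin A (Flna) rose 2.07-fold, Ankrd1 was 2.12-fold lower, and Egr2 at least 2.07-fold lower. TGF-beta responsive genes split 5 higher to 3 lower of 16 (6 and 4 adjusted over the list alone; camera adjusted p = 0.355), with Tgfb2 and Tgfb3 up 2.37-fold and 2.21-fold and Tgfbr3 2.04-fold lower. Growth factor signalling genes were higher in 2 and lower in 6 of 20 cases (2 and 6 adjusted over the list alone; camera adjusted p = 0.247): Igf1 rose by 3.32 on the log2 scale, while Fgf7 was 5.29-fold and the angiotensin receptor Agtr1a at least 3.24-fold lower.

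Matrix genes changed in both directions, and none of their 3 lists passed. Among 15 collagens, 5 were higher and 3 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.523): Col3a1 rose 3.95-fold, Col1a2 2.72-fold and Col1a1 2.44-fold, and the basement membrane collagen Col4a1 was 1.99-fold lower. Among 18 elastic fibre and matrix glycoprotein genes, 5 were higher and 5 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.473), with elastin (Eln) up 5.45-fold, fibulin Fbln2 2.64-fold and decorin (Dcn) 2.59-fold. Tenascin C (Tnc) rose 7.08-fold by its brightest probe, and another probe gave 0.35 (adjusted p = 0.162). Among 16 matrix proteases and inhibitors, 3 were higher and 5 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.864), with Plaur up 2.73-fold and cathepsin K (Ctsk) 3.34-fold lower.

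Target genes of LXR, a nuclear receptor that senses oxysterols, rose in 2 and fell in 5 of 10 cases (2 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.188). Of its 19 genes with a probe only these 10 were measured, and Abca1, Abcg1, Srebf1 and Mylip were not among them. The genes that rose, Scd1 and Scd2, also stand on the list of fatty acid synthesis and desaturation. Lpl and apolipoprotein E (Apoe) were 25.6-fold and 12.3-fold lower, and Nr1h3, the gene of LXR alpha, 3.45-fold lower. The desaturase gene Scd2 rose 3.38-fold, and Scd1, a close relative, 1.87-fold. Fatty acid synthesis and desaturation genes were higher in 4 and lower in 2 of 13 cases (5 and 2 adjusted over the list alone; camera adjusted p = 0.128), with Acacb 2.56-fold lower. Of 12 fatty acid oxidation genes, 1 was higher and 3 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.247), with Pdk4 5.46-fold and Acadm 1.66-fold lower. Of 22 oxidative phosphorylation genes 4 were higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.161), among them Cox5a by 1.64-fold.

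Most called genes of the cytokine, interferon and complement lists were lower in knockout cells, but these lists did not pass. Of 14 inflammatory cytokine and chemokine genes, 1 was higher and 6 lower (1 and 6 adjusted over the list alone; camera adjusted p = 0.220): Il33 was at least 9.65-fold higher, while the adhesion molecule Icam1, detected on 2 of 3 knockout arrays, was 7.57-fold, the neutrophil chemokine Cxcl1 3.50-fold and Cxcl16 3.28-fold lower. Of 14 type I interferon response genes, 0 were higher and 5 lower (0 and 5 adjusted over the list alone; camera adjusted p = 0.0626), with Gbp2 2.15-fold lower. Isg15 was 1.89-fold lower (adjusted p = 0.0427) and did not pass without knockout replicate 2 or 3 or without wild-type replicate 2 or 3 (adjusted p = 0.0573, 0.113, 0.123 and 0.0778). Of 9 complement genes, 2 were higher and 5 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.0908): the complement inhibitor Cd55 rose 3.70-fold, Cd59a was 2.60-fold lower, and C4a and C4b, near-identical copies, were 2.56-fold and 2.40-fold lower.

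Cyclins and cell cycle inhibitors split 4 higher to 1 lower of 13 (4 and 1 adjusted over the list alone; camera adjusted p = 0.285), with Ccnd1 up 2.63-fold, the inhibitor Cdkn2b up 2.15-fold and Cdkn1c 3.44-fold lower. Wnt and beta-catenin targets were higher in 5 and lower in 2 of 12 cases (5 and 2 adjusted over the list alone; camera adjusted p = 0.347), with Fzd2 up 3.02-fold and Wnt5a 1.81-fold, and the list's median was -0.09 but its mean 0.27. Of 9 Notch pathway genes 3 were higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.864; median 0.17, mean -0.05), with Notch1 2.29-fold lower and Hey2 1.42-fold higher. Of 13 NR4A receptor and immediate early genes, 3 were higher and 5 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.347), with Dusp1 up 2.12-fold. Egr3 was at least 3.95-fold lower, and another of its probes, with a knockout mean at background, gave -0.47 (adjusted p = 0.0778). Of 13 circadian clock genes, 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.523), with Bhlhe40 up 2.51-fold.

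Of 21 NRF2 and oxidative stress genes, 2 were higher and 4 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.523), with the glutathione transferases Gsta3 up 3.65-fold and Gsta4 2.88-fold lower. Of 11 heat shock genes, 2 were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.769), with Hsp90aa1 up 2.08-fold and Hsph1 2.55-fold lower. Of 16 p53 targets, 4 were higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.188), with Plk2 up 2.31-fold and Gadd45a 3.40-fold lower. Of 19 ribosomal protein genes 1 was lower, Rpl22 by 1.80-fold (0 and 1 adjusted over the list alone; camera adjusted p = 0.864; median 0.00, mean -0.01).

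The share of called genes near Fhl2 did not differ detectably from that elsewhere. Within 20 Mb of Fhl2, 31 of 87 genes were called (35.6%), against 31.3% of 8940 genes elsewhere (Fisher's exact test, two-sided p = 0.416). Of the 31 measured genes in the fixed list of neighbours, 7 were higher and 5 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.925), with Ecrg4 5.72-fold lower and Mfsd6 2.81-fold higher. Sgo2a (at least 2.29-fold) and Cavin2 (2.31-fold) were higher and Gulp1 (2.47-fold), Lonrf2 (2.13-fold) and Cflar (1.99-fold) lower, and Rftn2 fell by 1.59 on the log2 scale. Ercc5 was 1.86-fold lower by its brightest probe, and another gave -0.07. Of 7 listed marker genes of C57BL/6 substrains with a probe, only 3 were measured, and Nnt was not among them. Of these 3, Entpd4 was 1.42-fold higher (1 and 0 adjusted over the list alone). It did not pass without knockout replicate 2 (adjusted p = 0.0752) or wild-type replicate 2 (adjusted p = 0.0616). Among common reference genes, Gapdh, which also belongs to glycolysis, rose by 0.83 ± 0.12 (SE), Rplp0 gave 0.18 ± 0.15 (SE) and Actb 0.43 ± 0.15 (SE, adjusted p = 0.0681). The 4 other kept Actb probes did not pass either, and 2 of them changed in the same direction.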

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

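Removing probes of genes on chromosomes X and Y was chosen after the data were seen; all other alternatives were planned. The change of Fhl2 kept its direction and stayed past the threshold in all of them. Of 3018 comparisons of the 166 named genes past the threshold, 2970 kept direction and call, 48 lost the call, most of them with 1 array fewer, and 0 reversed. Comparisons in which the filter dropped the gene's probe are not among them. Genes detected in 1 genotype alone, such as Upk1b and Emcn, were not tested without an array of that genotype. Nor were they tested with detection required on all 6 arrays. Without background correction 2701 probes were higher and 2726 lower, with scaling to a common median 1963 and 2013, with no filter 1827 and 2005, with the authors' matrix 2116 and 2261, with at least a 1.5-fold change 1661 and 1764, and without chromosomes X and Y 2174 and 2278. Leaving out single arrays gave 1468 to 2190 higher and 1505 to 2048 lower probes, lowest without knockout replicate 2 and wild-type replicate 2; fewer samples were then tested.

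The gene lists depended on the test. With an estimated inter-gene correlation 0 lists were higher and 0 lower, and with fry, which does not compare with other genes, 14 were higher and 13 lower. Without background correction, with an intensity trend and robust prior and with the probes of a gene averaged, 6 lists were higher and 5 lower, and with median scaling, no filter or the replicate block 6 and 4; the cause was not tested. At a detection p under 0.01, 4 were higher and 3 lower, and with detection on all 6 arrays 5 and 2. With single arrays left out, 4 to 6 were higher and 2 to 5 lower, with 4 higher without any 1 knockout array. Endothelial markers had under 5 measured genes without any 1 wild-type array, and epithelial and mesothelial markers without any 1 knockout array, because the filter then kept fewer probes, so these lists could not be tested there. The same held for both with detection required on all 6 arrays, and for the epithelial and mesothelial list at a detection p under 0.01.

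Among named genes that did not pass, 29 comparisons gained a call, and 3 genes near 0 changed sign. Csf1r gave 0.0486 with cyclic loess, 0.0226 with median scaling and -0.0624 to 0.0914 without single arrays. Ncam1 gave 0.0584 with array weights and -0.365 to 0.122 without single arrays, and Mb -0.109 to 0.292 without single arrays.

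Deviations of same-numbered wild-type and knockout samples from their group means correlated at 0.118, 0.0727 and 0.0641, against at most 0.00863 for unlike numbers. All 6 samples correlated best with their own number, so a shared batch behind the numbers stays possible. Because the values were low and the labels do not say what the numbers share, the main fit did not pair the samples. With a replicate block 2147 probes were higher and 2258 lower, and 4140 of the 4596 calls were shared. Dim probes limit the comparison: 34.3% of probes passed the filter, and for probes near background the offset shrinks fold changes.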

Other observations

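The 4 lists of this paragraph and the next were drawn up after the data were seen, and their counts describe a pattern rather than test it. Hox genes, which code for transcription factors that mark position along the body axis, were lower in knockout cells in 9 of 15 measured cases and higher in 0. Hoxb7 was 4.36-fold lower, Hoxc9 4.28-fold, Hoxb5 4.03-fold and Hoxa5 3.43-fold, and Hoxd4 was not detected in knockout cells and at least 2.68-fold lower. The members that did not pass included Hoxb2, Hoxb4 and Hoxa4, at -0.33, -0.30 and 0.13.

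Imprinted genes were lower in 15 and higher in 3 of 30 cases. From the Dlk1-Dio3 cluster, Dlk1 and the noncoding Rian were not detected in knockout cells, at least 30.5-fold and 6.25-fold lower, and Dio3 was 4.66-fold lower. Peg3 was 3.44-fold and Grb10 3.39-fold lower, while Ppp1r9a, detected on 1 of 3 wild-type arrays with a wild-type mean at background, rose by 2.26 on the log2 scale, and Igf2 did not pass (-0.35, adjusted p = 0.156). Of 19 UDP-glucuronosyltransferase and aldehyde dehydrogenase genes, 10 were higher and 2 lower: besides Aldh3a1, Aldh1a7 rose 8.70-fold, and Ugt1a6b, Ugt1a6a and Ugt1a10, which share exons, rose 8.47-fold, 7.42-fold and 5.62-fold. Ugt1a7c, detected on 2 of 3 knockout arrays, gave -0.07 without passing. Of 6 X-linked genes that escape inactivation, 2 were higher and 2 lower. By chromosome, the 295 measured genes of chromosome 16 had a median change of -0.16 (camera adjusted p = 0.193) and the 231 of chromosome 18 one of 0.11 (camera adjusted p = 0.308).

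The tests in the following paragraphs were chosen after the results were seen, except the count without wild-type replicate 2, which was planned. Xist was not detected on any knockout array, by any of 4 probes. A mislabelled or swapped array is argued against by the arrays' own levels, since by Fhl2 and Xist 0 arrays lay nearer to the other genotype. Loss of Xist with an unchanged mix of male and female cells is argued against by the Y-linked Eif2s3y, which rose by 1.40 on the log2 scale. The other measured Y-linked genes moved less: Kdm5d rose by 0.79, and Uty gave 0.28 without passing. A candidate explanation is that knockout cultures held far fewer female cells than wild-type cultures: 2 of the 3 measured Y-linked genes rose and 0 fell, while Y-linked transcripts were also detected in wild-type cells. The 6 measured X-linked genes that escape inactivation did not move one way. Car5b and Kdm6a were lower, by -1.05 and -0.38, whereas Ddx3x rose by 1.06 and Mid1 was at least 1.14-fold higher. Pbdc1 and Eif2s3x gave -0.18 and -0.16 without passing. An effect of the genotype on the mix of male and female cells was not tested.

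Epithelial and mesothelial markers rose while endothelial markers fell. A lower share of smooth muscle cells in knockout cultures would raise both. With undetected members at their bound, the list medians lay 3.83 apart on opposite sides of 0. For comparison, 2 times the sum of their bootstrap standard errors was 3.71. The filter kept markers detected in only 1 genotype, here 3 of the 5 epithelial and mesothelial and 7 of the 10 endothelial ones. This sets the medians further apart, so their distance cannot decide the question. The direction of the endothelial markers, with 7 lower and 0 higher, still goes against a rise of both. A lower share would also lower genes of smooth muscle contraction. Of 16 measured, 6 were higher and 2 lower, and that list did not pass. Mesothelial or epithelial cells in the knockout cultures stay possible: of 13 listed genes with a probe, 6 were detected on at least 2 knockout arrays. Of the keratins, Krt7 was detected on 3 and Krt19 on 2 knockout arrays and both on 0 wild-type arrays, whereas Krt8 was detected on 1 and Krt18 on 0 knockout arrays. Endothelial cells in the wild-type cultures alone also stay possible, as 7 of 10 measured endothelial markers were lower, though Kdr, detected on 1 of 3 wild-type arrays, and Eng gave 0.30 and 0.69 without passing. All 20 listed endothelial genes had a probe, but only these 10 were detected on enough arrays to be kept. Neither can be told apart from a change of expression within smooth muscle cells, because all arrays of a genotype share them. Of the genes on these lists 0 stand on another list, and 9 of the 10 endothelial and 1 of the 5 mesothelial markers were detected on all wild-type arrays.

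The real split called 4596 probes, and the highest of the other splits of the 6 arrays called 0. As many were given by 1 of 10 splits, and with so few splits a share under 0.05 cannot be reached. Every other split also mixed both genotypes in each group. The genotype difference then widened the spread within groups, which alone keeps the count of probes low. For gene lists by camera the values were 8 and 5, again 1 of 10 splits. Part of the genotype difference remained between the mixed groups, so the lists called there do not measure false calls. The dim array of wild-type replicate 2 does not account for the number of probes, since 3188 were called without it. DNA of another strain around the deleted gene stays open as a contributor, also through effects on genes elsewhere, which were not tested: the odds ratio of a call within 20 Mb of Fhl2 was 1.22 (95% interval 0.756 to 1.92; Fisher's exact test, two-sided p = 0.416). An effect of the sex of the mice on autosomal genes cannot be told apart from the genotype, because Xist was detected on 0 knockout arrays and on all wild-type arrays.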
